A study of Caenorhabditis elegans with 6 samples.

How the data were processed

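RNA was taken from whole worms of strain N2, with 3 libraries from worms fed hda-5 RNAi bacteria and 3 from worms fed empty vector bacteria, grouped by their titles. Per the labels, polyadenylated RNA was selected, fragmented and copied with random primers, and sequenced in pairs on an Illumina instrument. Per the submitters' processing notes, the tools were Trim Galore, HISAT2 2.2.1, featureCounts, DESeq2 and StringTie. The labels name the genome build hg38, which is human, while the gene identifiers are C. elegans locus tags, so no coordinates are given. The deposited table holds 21005 rows with FPKM per library, computed by the authors; which program made the FPKM is not given in the sources used here. Per the file headers, the authors' pairwise comparisons come from EBSeq and edgeR, while the design text names DESeq2. Those columns hold the authors' log2 fold changes and FDR (an adjusted p-value), and a dash where a gene was not tested. Low FPKM values showed no whole-read steps, so read counts could not be recovered, and the depth and its counting error are unknown.

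Names came from RefSeq locus tags of C. elegans (assembly WBcel235, used for names only), which matched 19959 rows. Of the others, 1020 were genes new in the authors' annotation and 26 kept their tag name. Of 811 list members fixed by name, 798 had a row and 13 did not.

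The planned test was a count model, which FPKM values do not allow. The fallback fixed before the data were examined was used: limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(FPKM + 1), for genes with a mean of at least 1 FPKM, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The design leaves 4 residual degrees of freedom. Of 40 lists, 27 were fixed by name and 13 by symbol pattern. Lists were tested with camera (preset correlation 0.01, and an estimated correlation) and fry, and members were also adjusted over the list alone. Each library's list medians were set against 10000 random lists matched on mean expression in 20 bins. Enrichment of annotation terms among called genes could not be tested because 0 genes were called. In its place, chosen after seeing the data, camera was run on KEGG and GO terms of 10 to 500 tested genes.

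Genes named in the text were hda-5, a fixed set of 15 lipid genes, called genes of largest change, and, with none called, the 3 genes of smallest p in each direction. Genes outside this rule are said to be chosen after their values were seen, as were the 5 genes that passed only over their own list where the rule did not already name them. Simulated data with 200 changed genes tested the fit, giving 14.5%, 89% and 94% recovered at log2 changes of 1, 2 and 3, with 0, 11 and 12 false calls. For correlations of ratios that share a control, unchanged libraries were simulated 100 times with each gene's spread within the groups. A list shifted by 0.5 was called by camera with the preset (adjusted p = 3.5e-12) and the estimated correlation (adjusted p = 0.0450). The simulated genes were drawn independently, so this list, fatty acid synthesis, had an estimated correlation of -0.014. In the real data it had 0.14, and the median over lists was 0.17. Whether camera with an estimated correlation can find such a shift in these data is therefore not shown. Nor do the recovered shares of single genes show what limma would find in these data.

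Alternatives were another pseudocount (0.1), no filter, each library left out and a replicate block. Chosen after seeing the data were other scalings, library weights, robust moderation and a single control, for which the lone library is assumed to vary like the hda-5 RNAi libraries. How a gene list counts as reversed was also set after seeing the data: either the sign of its mean or camera's direction turned, where earlier versions used camera alone and then the mean alone. Figures were drawn with matplotlib 3.10.9, and the deposited comparisons were summarised with pandas 2.3.3.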

Results

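Whole-worm messenger RNA was measured in 6 libraries of Caenorhabditis elegans strain N2, the laboratory wild type of this nematode. From the first larval stage the worms ate bacteria producing double-stranded RNA against hda-5, a class II histone deacetylase gene, or bacteria with the empty vector, which gives no targeting RNA. There were 3 libraries of each kind. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Values were the authors' FPKM (fragments scaled by transcript length and by the number of mapped fragments), with no read counts, so the sequencing depth is unknown. FPKM totals were 716026, 717484 and 711331 in hda-5 RNAi 1, 2 and 3, and 714139, 775317 and 757667 in empty vector RNAi 1, 2 and 3. Between 12300 and 13214 genes per library reached 1 FPKM.

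The target was measured before any other gene. The hda-5 transcript (F43G6.11) had 2.67 ± 0.54 FPKM (SD, n = 3) after hda-5 RNAi and 6.37 ± 2.79 FPKM (SD, n = 3) with the empty vector. Its values were 2.29, 2.43 and 3.28 FPKM in hda-5 RNAi 1, 2 and 3, against 8.53, 3.22 and 7.35 FPKM in the empty vector libraries. The library labelled empty vector RNAi 2 therefore lay just under the highest hda-5 RNAi library, against its label, and every direction given here rests partly on it. On the log2(FPKM + 1) scale the difference was -0.93 (SE 0.33), with an adjusted p of 0.440 in limma, and it did not pass the threshold. An exact two-sided permutation test gave p = 0.2, where 3 against 3 libraries cannot go below 0.1. Reads from the fed double-stranded RNA could also fall on this gene.

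The comparison of hda-5 RNAi with the empty vector asked which transcripts depend on this deacetylase, with lipid metabolism as the study's subject. Of 12968 genes tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.440. At an unadjusted p under 0.05 there were 1444 genes, 652 with higher and 792 with lower values, where 648 would be reached by chance. The 2 groups did not overlap for 2508 genes (19.3%, against 10% by chance), and 167 of these were at least 2-fold higher and 179 at least 2-fold lower. The 3 genes of smallest p in each direction did not pass: T27A1.3 (log2 difference 1.88), Y38E10A.22 (1.08) and the histone gene his-40 (1.52) had higher values, and C27F2.10 (-1.31), the glutathione S-transferase gene gst-24 (-1.56) and oig-3 (-1.08) had lower values. The count of 1444 was 615 without hda-5 RNAi 2, 666 without hda-5 RNAi 3, 2344 without empty vector RNAi 1 and 887 without empty vector RNAi 3. In simulated data of this size, with 200 changed genes, limma recovered 14.5% of genes changed by 1 on the log2 scale and 89% of those changed by 2. The simulated genes were drawn independently, while in the real data the median estimated correlation over gene lists was 0.17. The number of truly changed genes is also unknown. Whether limma would find changes of 1 or 2 in these libraries is therefore not shown.

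Mitochondrial beta-oxidation, which shortens fatty acids for energy, lay higher after hda-5 RNAi by camera. Its 25 measured genes had a median log2 difference of 0.35, with 20 positive and 11 at an unadjusted p under 0.05, and camera placed the list above other genes (adjusted p = 1.1e-04; adjusted p = 0.615 with an estimated correlation, so the call rests on the preset correlation of 0.01). Median deviations of the list from the mean of all 6 libraries were 0.11, 0.25 and 0.39 in hda-5 RNAi 1, 2 and 3, but 0.05 in empty vector RNAi 1 and -0.34 and -0.39 in the libraries labelled empty vector RNAi 2 and 3, so empty vector RNAi 1 lay nearest to hda-5 RNAi 1. The acyl-CoA synthetase gene acs-2 had 79.0 ± 27.4 FPKM (SD, n = 3) after hda-5 RNAi and 28.5 ± 2.49 FPKM (SD, n = 3) with the empty vector. Its log2 difference of 1.39 (SE 0.24) passed only when adjusted over the list alone (adjusted p = 0.0185 in limma, 0.440 over all genes). Some carnitine palmitoyltransferase genes, named after their values were seen, had log2 differences of 1.02 for cpt-1, 0.67 for cpt-2 and 1.43 for cpt-4, none past the threshold. The list also holds cpt-3, cpt-5 and cpt-6, whose values are not given, and 5 of its 25 genes were negative, so the genes shown do not stand for the family. The mean of the list was 0.30 with all 6 libraries and 0.18 without hda-5 RNAi 3. The call for acs-2 ended in 3 of 17 alternatives, in which its log2 difference was 1.39 or more: without the library labelled empty vector RNAi 2 (1.4, adjusted p = 0.0695 over the list alone in limma), without a filter (1.39, adjusted p = 0.0747), and with empty vector RNAi 1 as the only control, chosen after seeing the data (1.52, adjusted p = 0.215).

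Peroxisomal beta-oxidation and ascaroside synthesis genes lay higher too, with a median log2 difference of 0.36 over 22 genes and 20 positive (camera adjusted p = 4.8e-04; adjusted p = 0.615 with an estimated correlation). The library labelled empty vector RNAi 2 deviated by -0.72 in this list, by its median, and empty vector RNAi 1 and 3 by 0.06 and 0.03. Without the library labelled empty vector RNAi 2 the mean log2 difference was 0.06 in place of 0.36 and the call was lost (camera adjusted p = 0.379), as it was against empty vector RNAi 1 alone (mean 0.04, adjusted p = 0.508). Central carbon genes of glycolysis, gluconeogenesis and the glyoxylate and tricarboxylic acid cycles had a median of 0.10 over 39 genes (camera adjusted p = 0.0376; adjusted p = 0.615 with an estimated correlation). That call was lost without hda-5 RNAi 2 (camera adjusted p = 0.0966), empty vector RNAi 1 (0.0845) or the library labelled empty vector RNAi 2 (0.174), although the mean log2 difference was 0.14, 0.13 and 0.13 there and 0.13 with all 6 libraries. Under upper-quartile scaling, chosen after seeing the data, the mean was 0.09 and the call ended too (camera adjusted p = 0.0795).

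Fatty acid synthesis, desaturation and elongation did not pass camera as a list (26 genes, median log2 difference 0.12, mean 0.21, adjusted p = 0.0814). It did pass without hda-5 RNAi 3 (mean 0.28, camera adjusted p = 0.00362) or empty vector RNAi 1 (mean 0.30, camera adjusted p = 0.0194), and had a mean of 0.15 without the library labelled empty vector RNAi 2 (camera adjusted p = 0.541). Within it the delta-9 desaturase gene fat-6, which makes monounsaturated fatty acids, had 904 ± 172 FPKM (SD, n = 3) against 370 ± 126 FPKM (SD, n = 3). Its log2 difference of 1.32 (SE 0.27) passed only when adjusted over the list alone (adjusted p = 0.0494 in limma, 0.440 over all genes), and 0 other members did. That call was lost without hda-5 RNAi 2, hda-5 RNAi 3, the library labelled empty vector RNAi 2 or empty vector RNAi 3, with log2 differences of 1.19, 1.3, 1.15 and 1.23 and adjusted p = 0.237, 0.216, 0.150 and 0.182 over the list alone in limma. It ended in 15 of 17 alternatives, with log2 differences of 0.80 to 1.39 and adjusted p from 0.0503 to 0.634 over the list alone. Reads of fat-6 and its near-identical copy fat-7 can be split between them, so both are uncertain. The log2 difference was 0.98 for fat-7, 1.44 for the palmitoyl-CoA desaturase gene fat-5 and 0.47 for fat-2, none past the threshold. Over 17 alternatives it ranged from 0.38 to 1.29 for fat-7 and from 1.08 to 2.04 for fat-5. The acetyl-CoA carboxylase gene pod-2 (-0.13) and the fatty acid synthase gene fasn-1 (-0.32) did not pass either. The direction of pod-2 turned without hda-5 RNAi 3 (0.058), empty vector RNAi 1 (0.0048) or empty vector RNAi 3 (0.015), and that of fat-2 against empty vector RNAi 1 alone (-0.040). The log2 difference of fat-2 was 0.22 without the library labelled empty vector RNAi 2 and 0.73 without empty vector RNAi 1.

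Of the regulators of lipid genes, 0 passed the test. Log2 differences were 0.30 for the nuclear receptor gene nhr-49, 0.25 for nhr-80, 0.04 for sbp-1 (the SREBP homologue) and 0.05 for the Mediator subunit gene mdt-15. The triacylglycerol lipase gene atgl-1 (0.08), the lysosomal lipase gene lipl-4 (0.12), the acyltransferase gene dgat-2 (0.74) and the yolk protein gene vit-2 (0.72, at 1.59 against 0.55 FPKM) did not pass. Over 17 alternatives the log2 difference was 0.26 to 0.99 for dgat-2 and 0.18 to 0.37 for nhr-49. Several of the other directions turned with 1 library left out. Without the library labelled empty vector RNAi 2 the log2 difference was -0.30 for sbp-1, -0.035 for nhr-80, -0.10 for mdt-15 and -0.14 for atgl-1, and without empty vector RNAi 3 it was -0.21 for lipl-4. Without hda-5 RNAi 1 it was -0.056 for sbp-1, -0.0037 for mdt-15 and -0.038 for atgl-1, without hda-5 RNAi 2 -0.060 for sbp-1, and without hda-5 RNAi 3 -0.020 for lipl-4. Upper-quartile scaling turned sbp-1 to -0.0039, and library weights turned sbp-1 (-0.013) and atgl-1 (-0.10), both chosen after seeing the data. The remaining lipid lists did not pass camera with all 6 libraries. Median log2 differences and camera adjusted p were 0.18 and 0.0814 for lipases and lipolysis (15 genes), and 0.16 and 0.0819 for triacylglycerol synthesis and lipid droplet proteins (20 genes). They were 0.12 and 0.233 for sphingolipid metabolism (25 genes), 0.04 and 0.228 for transcriptional regulators of lipid metabolism (29 genes), and 0.06 and 0.204 for lipid-binding and yolk proteins (21 genes). Phospholipid synthesis (23 genes) had a median of -0.04 (camera adjusted p = 0.501), and the sign of its mean turned with equal FPKM totals. Several of these lists depended on the libraries kept. Leaving out the library labelled empty vector RNAi 2 gave a mean of 0.028 in place of 0.18 for lipolysis (camera adjusted p = 0.800), 0.24 in place of 0.32 for triacylglycerol synthesis (0.583), -0.11 in place of 0.11 for sphingolipid metabolism (0.280) and 0.024 in place of 0.15 for the transcriptional regulators (0.473). Lipolysis passed without hda-5 RNAi 3 (mean 0.25, camera adjusted p = 0.0247), empty vector RNAi 1 (0.31, 0.0306) or a filter (0.21, 0.0122). Triacylglycerol synthesis passed without hda-5 RNAi 3 (0.34, 0.0255), empty vector RNAi 1 (0.36, 0.0226) or empty vector RNAi 3 (0.36, 0.0232). Without empty vector RNAi 3, sphingolipid metabolism (0.28, 0.0109) and the transcriptional regulators (0.20, 0.0151) passed too. Against empty vector RNAi 1 alone, phospholipid synthesis had a mean of -0.12 (camera adjusted p = 0.0279), a test in which the spread comes from the hda-5 RNAi libraries and the lone control is assumed to vary like them. Among histone modifiers, deacetylases and sirtuins had a median of -0.01 over 11 genes (camera adjusted p = 0.747), and acetyltransferases and acetyl-lysine readers 0.19 over 12 genes (camera adjusted p = 0.106). The acetyltransferase list, with a mean of 0.21, had 0.29 without empty vector RNAi 1 (camera adjusted p = 0.0414) and 0.10 without the library labelled empty vector RNAi 2 (0.473).

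**Figure D1:**
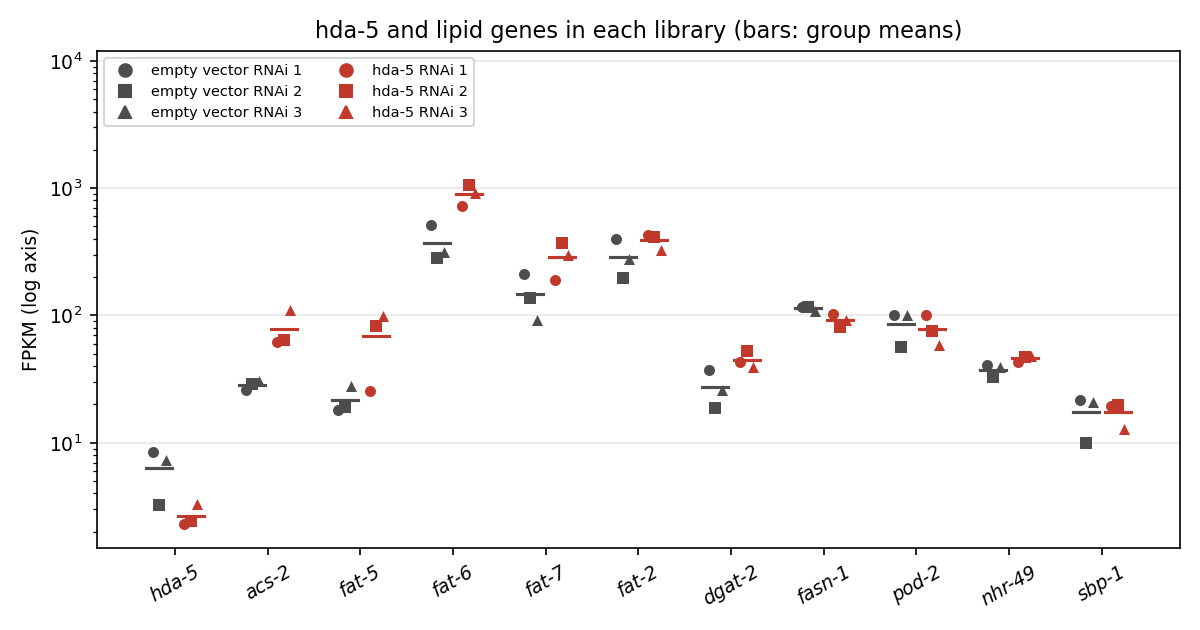
FPKM (log axis) of hda-5 and 10 lipid genes in each of the 6 libraries, with grey marks for empty vector RNAi, red marks for hda-5 RNAi, a shape per replicate number and bars for group means. The library labelled empty vector RNAi 2 lies at 3.22 FPKM for hda-5, under hda-5 RNAi 3, and for acs-2 the groups do not overlap (means of 79.0 and 28.5 FPKM).

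Autophagy and stress lists lay higher after hda-5 RNAi by camera. Autophagy and lysosomal genes had a median log2 difference of 0.26, with 37 of 40 positive (camera adjusted p = 7.2e-05; adjusted p = 0.615 with an estimated correlation). Heat shock, unfolded protein and oxidative stress genes had a median of 0.30 over 36 genes (camera adjusted p = 0.00665), and genes raised by active DAF-16 0.64 over 17 genes (camera adjusted p = 7.2e-04), each with adjusted p = 0.574 with an estimated correlation. The small heat shock gene hsp-17 had 404 ± 77.3 FPKM (SD, n = 3) against 197 ± 27.5 FPKM (SD, n = 3), a log2 difference of 1.02 that passed only when adjusted over the list alone (adjusted p = 0.0431 in limma). Of hsp-16.2, named after its values were seen, the libraries had 165 to 232 FPKM after hda-5 RNAi, and 131, 7.92 and 1.6 FPKM in empty vector RNAi 1, 2 and 3. This gene belongs to both the stress and the DAF-16 lists, which share several members, so the shifts of these lists are not separate results. Leaving out the library labelled empty vector RNAi 2 ended the calls of autophagy genes (mean 0.15 in place of 0.33, camera adjusted p = 0.199) and stress genes (mean 0.62 in place of 0.70, camera adjusted p = 0.0873). Against empty vector RNAi 1 alone the autophagy call ended as well (mean 0.09, camera adjusted p = 0.470). The means against that control were 0.20 for stress genes, in place of 0.70, and 0.49 for genes raised by active DAF-16, in place of 0.94. That test takes its spread from the hda-5 RNAi libraries alone. The call of hsp-17 was lost without hda-5 RNAi 2, hda-5 RNAi 3, the library labelled empty vector RNAi 2 or empty vector RNAi 3, with log2 differences of 0.98, 0.90, 0.93 and 1.01 and adjusted p = 0.194, 0.181, 0.154 and 0.151 over the list alone in limma. It ended in 10 of 17 alternatives, with log2 differences of 0.81 to 1.03.

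C-type lectins had a median log2 difference of 0.28 over 88 genes (camera adjusted p = 8.0e-04), intracellular pathogen response genes 0.37 over 16 genes (0.0174), secreted immune effectors 0.21 over 45 genes (0.0400) and UDP-glucuronosyltransferases 0.19 over 46 genes (0.0274). With an estimated correlation the adjusted p was 0.615, 0.615, 0.634 and 0.726 for these lists. Without the library labelled empty vector RNAi 2 the mean was 0.15 in place of 0.30 for C-type lectins (camera adjusted p = 0.320), 0.21 in place of 0.29 for the pathogen response (0.203), 0.01 in place of 0.20 for immune effectors (0.852) and -0.0045 in place of 0.20 for UDP-glucuronosyltransferases (0.770), and camera's direction turned for the last 2 lists. The mean of immune effectors was 0.33 without empty vector RNAi 3, and that of UDP-glucuronosyltransferases 0.32 without empty vector RNAi 1. Against empty vector RNAi 1 alone the means were 0.03, 0.20, 0.09 and -0.03 for these lists, and 0 of them passed. Leaving out hda-5 RNAi 1 also ended the calls of the pathogen response (camera adjusted p = 0.0697), immune effectors (0.148) and UDP-glucuronosyltransferases (0.168), and leaving out hda-5 RNAi 2 those of immune effectors (0.115) and UDP-glucuronosyltransferases (0.151). With all libraries kept, the calls of C-type lectins (mean 0.11, camera adjusted p = 0.188) and UDP-glucuronosyltransferases (0.14, 0.0889) ended without a filter, and that of immune effectors ended with equal FPKM totals (0.26, 0.0815), chosen after seeing the data. Over 16 alternatives these calls ended in 3 for C-type lectins, 3 for the pathogen response, 8 for immune effectors and 8 for UDP-glucuronosyltransferases. Histone genes, a multigene family whose reads can be split between copies, had a median of 0.51 over 68 genes (camera adjusted p = 3.5e-07; adjusted p = 0.615 with an estimated correlation). Among them his-40 had 11.2 ± 3.05 FPKM (SD, n = 3) against 3.18 ± 0.40 FPKM (SD, n = 3) and passed only when adjusted over the list alone (adjusted p = 0.0274 in limma). Its log2 difference of 1.52 was 1.4 without hda-5 RNAi 2, 1.4 without hda-5 RNAi 3, 1.52 without the library labelled empty vector RNAi 2 and 1.58 without empty vector RNAi 3, and the call was lost in each (adjusted p = 0.177, 0.164, 0.0991 and 0.0731). It ended in 7 of 17 alternatives. With empty vector RNAi 1 as the only control, chosen after seeing the data, the mean of the histone list was 0.08 in place of 0.45 (camera adjusted p = 0.347), and without empty vector RNAi 3 it was 0.27. Median deviations of the histone list were 0.19, 0.18 and 0.43 in hda-5 RNAi 1, 2 and 3 and 0.19 in empty vector RNAi 1, but -0.42 and -0.59 in the libraries labelled empty vector RNAi 2 and 3.

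Cytosolic ribosomal protein genes lay lower, with a median log2 difference of -0.35 and 63 of 65 negative (camera adjusted p = 1.5e-12; adjusted p = 0.615 with an estimated correlation). The libraries did not share this shift evenly. Median deviations of the list from the mean of all 6 libraries were 0.35 and 0.25 in the libraries labelled empty vector RNAi 2 and 3, but -0.07 in empty vector RNAi 1 and -0.09, -0.18 and -0.23 in hda-5 RNAi 1, 2 and 3. Against empty vector RNAi 1 alone the mean log2 difference of the list was 0.03, where it was -0.29 with all controls, although camera still placed the list below other genes (adjusted p = 0.00927, with the spread taken from the hda-5 RNAi libraries alone). Without the library labelled empty vector RNAi 2 the mean was -0.12, and without empty vector RNAi 1 it was -0.45.

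Camera also called lists of tissue and stage markers, although single libraries of the 2 groups overlapped in several of them. Mitotic and meiotic germline genes had a median log2 difference of -0.28 over 35 genes (camera adjusted p = 5.5e-04), oocyte and eggshell genes -0.18 over 35 genes (0.0404), muscle genes -0.16 over 32 genes (0.00433) and neuronal genes -0.14 over 35 genes (0.0376). With an estimated correlation the adjusted p was 0.628, 0.766, 0.615 and 0.615. Adult cuticle collagens had a median of 1.84 over 7 genes (camera adjusted p = 0.0174), sperm genes 0.25 over 27 genes (0.0439) and intestinal genes 0.23 over 33 genes (0.0376), with adjusted p = 0.615, 0.766 and 0.766 with an estimated correlation. Median deviations of sperm genes from the mean of all 6 libraries were 0.03, -0.10 and 0.54 in hda-5 RNAi 1, 2 and 3, against -0.23, 0.60 and -0.78 in the empty vector libraries. Those of intestinal genes were 0.26, 0.26 and -0.21 against 0.23, -0.88 and 0.34. In empty vector RNAi 3 the adult cuticle list lay 3.72 below the mean of all libraries by its median (log2 deviation -3.72), and in the library labelled empty vector RNAi 2 the germline list deviated by 0.56. The mean of the adult cuticle list was 1.94, but 0.55 without empty vector RNAi 3, and its call ended without a filter (mean 1.51, camera adjusted p = 0.0997). Collagens of the col class lay lower by camera (123 genes, adjusted p = 0.0161; adjusted p = 0.739 with an estimated correlation) although their median was 0.04 and their mean -0.20.

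The means of these marker lists moved with single libraries. For germline genes the mean of -0.27 was -0.07 without the library labelled empty vector RNAi 2, where the call was lost (camera adjusted p = 0.111), and -0.40 without empty vector RNAi 3. For muscle genes the mean of -0.19 was -0.11 without the library labelled empty vector RNAi 2, with the call held, and -0.13 with library weights, chosen after seeing the data, where it ended (camera adjusted p = 0.0643). Neuronal genes had -0.17, and their call was lost without hda-5 RNAi 2, the library labelled empty vector RNAi 2 or empty vector RNAi 3 (means -0.12, -0.11 and -0.17, camera adjusted p = 0.0665, 0.153 and 0.0738). Oocyte genes had -0.13, with 0.08 without the library labelled empty vector RNAi 2 (camera adjusted p = 0.901). Their call was also lost without hda-5 RNAi 1, hda-5 RNAi 2 or empty vector RNAi 1 (means -0.12, -0.015 and -0.17, camera adjusted p = 0.148, 0.311 and 0.0571), while the mean was -0.26 without hda-5 RNAi 3 and -0.31 without empty vector RNAi 3. Sperm genes had 0.27, with -0.04 without empty vector RNAi 3 (camera adjusted p = 0.960) and 0.67 without the library labelled empty vector RNAi 2. Their call was lost too without hda-5 RNAi 1, hda-5 RNAi 3 or empty vector RNAi 1 (means 0.31, 0.076 and 0.19, camera adjusted p = 0.0531, 0.446 and 0.210). Intestinal genes had 0.25, with -0.11 without the library labelled empty vector RNAi 2, 0.41 without empty vector RNAi 1 and 0.44 without empty vector RNAi 3, and their call was lost without hda-5 RNAi 1 or hda-5 RNAi 2 (means 0.20 and 0.18, camera adjusted p = 0.139 and 0.159). The mean of col genes was -0.012, -0.11 and -0.49 without hda-5 RNAi 1, 2 and 3, and -0.43, 0.14 and -0.30 without each empty vector library in turn, and the call was lost without hda-5 RNAi 1 (camera adjusted p = 0.615) and without the library labelled empty vector RNAi 2 (0.473). Over 16 alternatives the calls of oocyte, sperm, neuronal, intestinal and col genes ended in 8, 8, 9, 9 and 4.

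**Figure D2:**
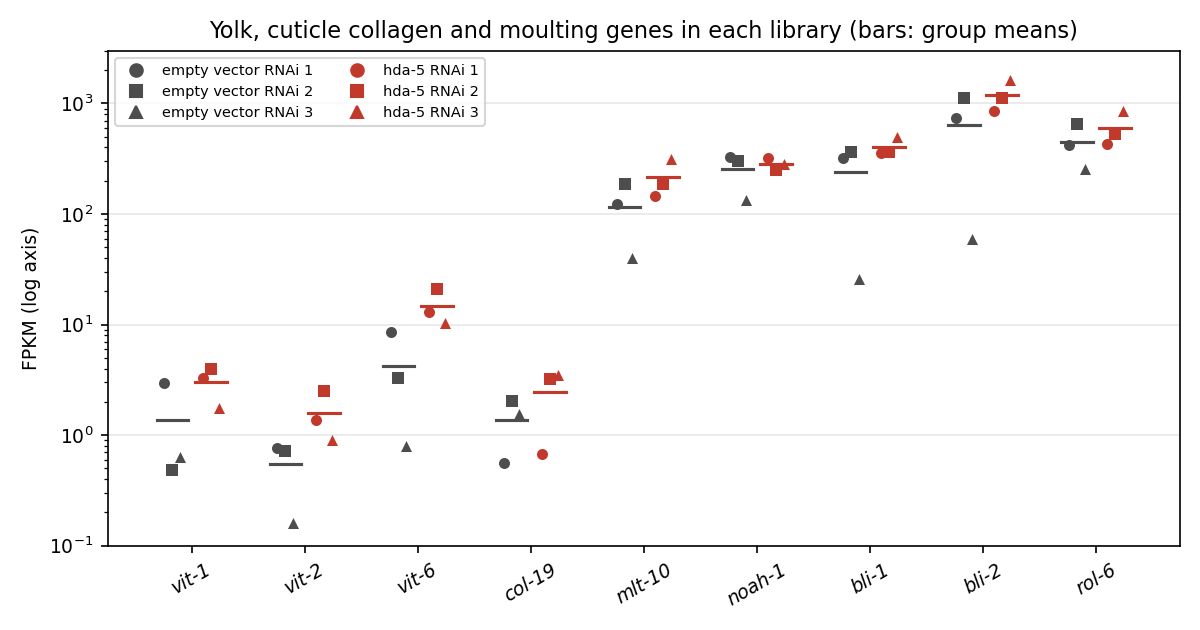
FPKM (log axis) of yolk genes (vit), cuticle collagen genes (col-19, bli-1, bli-2, rol-6) and moulting genes (mlt-10, noah-1) in each of the 6 libraries, with grey marks for empty vector RNAi, red marks for hda-5 RNAi and bars for group means. No library passes 21.1 FPKM for vit-6, and empty vector RNAi 3 is lowest for bli-1 at 25.6 FPKM, where the other libraries have 324 FPKM or more.

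The other lists did not pass camera with all 6 libraries. Moulting and larval cuticle genes had a median log2 difference of 0.46 over 44 genes (adjusted p = 0.0634), major sperm protein genes 0.40 over 28 (0.0553), early zygotic embryonic genes -0.11 over 10 (0.0963), and cytochrome P450 genes 0.18 over 44 (0.0963). Glutathione S-transferases had -0.05 over 36 genes (0.138), with gst-24 at 8.13 ± 2.20 FPKM (SD, n = 3) against 26.2 ± 7.88 FPKM (SD, n = 3), which passed only when adjusted over the list alone (adjusted p = 0.0248 in limma). Its log2 difference of -1.56 was -1.43 without hda-5 RNAi 2, -1.51 without hda-5 RNAi 3 and -1.6 without empty vector RNAi 3, and the call was lost in each (adjusted p = 0.130, 0.134 and 0.0739). It ended in 6 of 17 alternatives. F-box genes had 0.07 over 108 genes (0.106), nuclear hormone receptors 0.08 over 172 (0.351), chemoreceptors 0.15 over 36 (0.191), proteasome subunits 0.07 over 32 (0.204) and nuclear-encoded respiratory chain subunits -0.04 over 43 (0.251). Insulin signalling genes had a median of 0.12 and a mean of -0.11 over 18 genes (0.876). Major sperm protein genes passed in 8 of 15 alternatives, among them without hda-5 RNAi 1 (mean 0.61, camera adjusted p = 0.00777), hda-5 RNAi 2 (0.51, 0.0213) or the library labelled empty vector RNAi 2 (0.99, 4.9e-10), but their mean was -0.083 without empty vector RNAi 3 (0.817). Moulting genes passed in 5 of 16, among them without hda-5 RNAi 2 (0.44, 0.0336) or the library labelled empty vector RNAi 2 (0.64, 0.00155), but their mean was -0.0088 without empty vector RNAi 3 (0.895). Cytochrome P450 genes passed without hda-5 RNAi 3 (0.20, 0.0215) or empty vector RNAi 1 (0.24, 0.0405), and F-box genes (0.22, 0.00887) and nuclear hormone receptors (0.10, 0.0120) without empty vector RNAi 3. The means of these lists were 0.12 (0.473), 0.12 (0.583) and -0.016 (0.199) without the library labelled empty vector RNAi 2. Without the library labelled empty vector RNAi 2, glutathione S-transferases passed with lower values (-0.20, 0.0314) and proteasome subunits with higher ones (0.07, 0.0199), while without empty vector RNAi 3 their means were -0.068 (0.960) and -0.068 (0.849). Of all 40 lists, camera with the preset correlation called 14 higher and 6 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.574). Without the library labelled empty vector RNAi 2 it called 8 higher and 3 lower, and with empty vector RNAi 1 as the only control, a test without a spread among controls, 7 higher and 4 lower. The directional fry test passed 0 (smallest adjusted p = 0.244), and its test for change in either direction passed 0 (smallest adjusted p = 0.184).

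**Figure D3:**
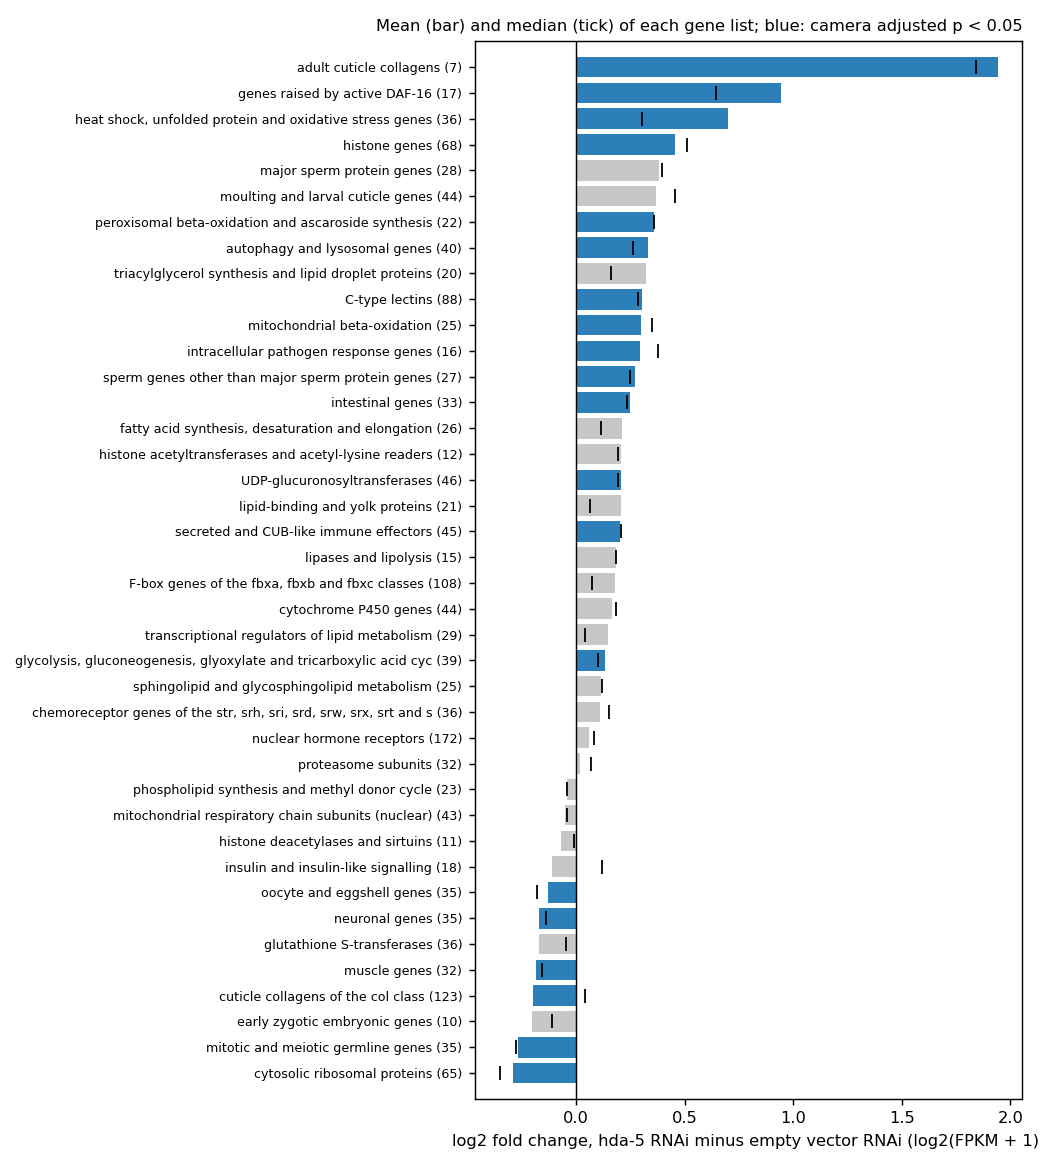
Mean (bar) and median (tick) log2 difference, hda-5 RNAi minus empty vector RNAi on the log2(FPKM + 1) scale, of each of 40 gene lists, with the number of measured genes in parentheses and blue for lists past camera's adjusted p of 0.05 with the preset correlation. Adult cuticle collagens have the highest median (1.84, 7 genes, with a mean of 1.94 that is 0.55 without empty vector RNAi 3) and cytosolic ribosomal proteins the lowest (-0.35, 65 genes), with bars and ticks on opposite sides of 0 for col collagens and insulin signalling.

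The authors' deposited table also holds comparisons of 1 library named HT-1 with each of 5 named H5-1 to H5-5. The edgeR columns of the authors' deposited table for H5-1, H5-3 and H5-4 match the FPKM ratios of hda-5 RNAi 1, 2 and 3 over empty vector RNAi 1. With a constant offset taken out, the median absolute difference was 0.001 on the log2 scale. At the authors' FDR of 0.01 and 2-fold change, the authors' deposited table calls 142 genes higher and 76 lower in H5-1, 426 and 335 in H5-3, and 1546 and 485 in H5-4. For hda-5 the authors' deposited table gives log2 fold changes of -1.93, -1.78 and -1.42 in these comparisons, for acs-2 1.24, 1.33 and 2.05, and for fat-6 0.48, 1.1 and 0.80. In H5-2 and H5-5, which match no library analysed here, the authors' deposited table gives 0.28 and -4.19 for acs-2 and -0.95 and -0.38 for fat-6. The authors' deposited table compares single libraries against 1 shared control, so these calls have no replicate check.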

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

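Both results here were chosen after seeing the data. In the authors' deposited table, the edgeR comparison of HT-1 with H5-2 calls 1377 genes (865 higher, 512 lower) and that with H5-5 calls 2810 genes (1415 higher, 1395 lower). With a constant offset taken out, neither of these comparisons matches any pair of the 6 FPKM columns within a median absolute difference of 0.01 on the log2 scale. They were set aside as a signal in data outside the main comparison, and the names are not labels of any sample used here. For hda-5 the authors' deposited table gives log2 fold changes of -1.89 in H5-2 and -0.15 in H5-5. Those of acs-2 are 0.28 and -4.19 and those of fat-6 are -0.95 and -0.38 in the authors' deposited table. The fold changes of fat-6 are thus negative in both comparisons, and those of acs-2 differ in sign. Of these acs-2 and fat-6 values, only the -4.19 of acs-2 in H5-5 reaches the authors' 2-fold change. With 1 library on each side the signs have no replicate check. Across genes, the authors' deposited fold changes of H5-2 had Pearson's r of 0.765 with the FPKM ratio of the library labelled empty vector RNAi 2 over empty vector RNAi 1, and from -0.01 to 0.567 with the other 4 libraries. Those of H5-5 had r of 0.736 with empty vector RNAi 3, and from -0.163 to 0.01 with the other 4 libraries. Genes are not independent replicates, and all these ratios share 1 control library. Simulated unchanged libraries that share a control gave a mean r of 0.502 and a covariance of 0.194, against an observed covariance of 0.337 for H5-2 and 0.537 for H5-5. The simulation gave every library the same spread, which includes the distances between the controls. Its r is not a measured chance level, since other libraries over the same control gave -0.163 to 0.01 for H5-5 and up to 0.567 for H5-2.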

How the results depend on the processing

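The single-control, scaling, weighting and robust alternatives were chosen after seeing the data, as was the rule by which a list reverses (its mean or camera's direction). Count-based alternatives (DESeq2, voom, edgeR factors, library sizes and count filters) were not run because the values are FPKM, and depth cannot be judged. With a single control the spread comes from the hda-5 RNAi libraries, and the lone control is assumed to vary like them. Values are mean log2 differences unless stated, and the cause was not tested for any change below.

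Genes called higher stayed at 0 and lower at 0 except without a filter (1 lower, T09E8.4), with empty vector RNAi 1 as the only control (1 higher, mboa-2, and 1 lower, C25D7.10) and with a library left out (0 to 1 higher, 0 to 1 lower: vpr-1, col-93, mboa-2, C25D7.10), all named after their values were seen. Genes at an unadjusted p under 0.05 numbered 218 with that single control and 615 to 2344 with a library left out. Lists higher by camera numbered 7 with that control, 0 with an estimated correlation and 8 to 18 with a library left out. Lists lower numbered 0 with an estimated correlation and 3 to 6 with a library left out. For hda-5 the range was -1.29 to -0.71 with a library left out.

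With the replicate block, 0 genes were called and 912 had an unadjusted p under 0.05. Same-numbered libraries did not deviate together from their group means (correlations 0.04, -0.28 and -0.27). Since the controls stand far apart, the deviation of each depends on the others, so this cannot tell whether the numbers pair the libraries. Of all pairs, hda-5 RNAi 1 and empty vector RNAi 1 lay nearest (root mean square log2 difference 0.297). The same-numbered libraries 2 and 3 lay 0.759 and 0.924 apart. The block ended the camera calls of oocyte, sperm and neuronal genes (adjusted p = 0.0514 each) and the calls over their own list of fat-6, hsp-17, gst-24 and his-40.

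Of 20 lists called by camera, 17 lost the call in at least 1 of 16 alternatives (robust moderation moves no list), and 11 in at least 1 that kept all 6 libraries. Of 20 lists not called, 14 gained a call in at least 1. No filter ended the calls of oocyte, intestinal, UDP-glucuronosyltransferase, adult cuticle, neuronal and C-type lectin lists (adjusted p = 0.0552 to 0.188). Equal totals ended those of UDP-glucuronosyltransferase, neuronal, intestinal, sperm and immune lists (0.0522 to 0.0815), upper-quartile scaling those of oocyte, col and central carbon lists (0.0557 to 0.0795), and library weights those of UDP-glucuronosyltransferase, neuronal, immune, muscle and intestinal lists (0.0511 to 0.117).

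With empty vector RNAi 1 as the only control, fat-2 (-0.040), sbp-1 (-0.32), nhr-80 (-0.19), mdt-15 (-0.19) and atgl-1 (-0.17) turned negative. So did lipolysis (-0.073), sphingolipid (-0.067), intestinal (-0.082) and UDP-glucuronosyltransferase (-0.029) lists. The means of ribosomal proteins (0.031) and col collagens (0.28) turned positive, while camera's direction stayed down for both (adjusted p = 0.00927 and 0.784). Camera's direction alone turned for deacetylases (-0.032), fatty acid synthesis (0.022), lipid regulators (0.0037) and C-type lectins (0.035). Library weights gave sbp-1 -0.013 and atgl-1 -0.10, and upper-quartile scaling sbp-1 -0.0039. Phospholipid synthesis turned to 0.022 with equal totals, 0.0085 without the 20 most abundant genes and 0.023 without msp and vit genes. Camera's direction turned for deacetylases with equal totals (-0.012) and without msp and vit genes (-0.012).

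With a library left out, the ranges of results that turned were -0.40 to 0.058 (pod-2), -0.30 to 0.24 (sbp-1), -0.035 to 0.47 (nhr-80), -0.10 to 0.17 (mdt-15), -0.14 to 0.20 (atgl-1) and -0.21 to 0.43 (lipl-4). For lists they were -0.091 to -0.044 (deacetylases, camera only), -0.071 to -0.0016 (phospholipid, camera only), -0.11 to 0.28 (sphingolipid), 0.024 to 0.22 (lipid regulators, camera only), 0.010 to 0.33 (immune, camera only), -0.31 to 0.085 (oocyte, mean only), -0.037 to 0.67 (sperm, mean only), -0.11 to 0.44 (intestinal), -0.49 to 0.14 (col, mean only) and -0.0045 to 0.32 (UDP-glucuronosyltransferases). The sign of the mean also turned for moulting genes (-0.0088 to 0.64), major sperm protein genes (-0.083 to 0.99), proteasome subunits (-0.068 to 0.072) and nuclear hormone receptors (-0.016 to 0.10).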

Other observations

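All tests in this part were chosen after the result was seen. Annotation terms gave a view not limited to the fixed lists. Of 120 KEGG pathways, camera with the preset correlation placed 14 higher and 6 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.820). Fatty acid degradation had a median log2 difference of 0.28 over 58 genes, with 15 at an unadjusted p under 0.05 and higher and 0 lower (camera adjusted p = 2.5e-04). Peroxisome genes had 0.29 over 89 genes (camera adjusted p = 3.7e-05), ribosome biogenesis -0.35 over 73 genes (2.2e-09) and RNA polymerase -0.40 over 27 genes (1.4e-08). Of 722 GO terms 34 were higher and 38 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.975). The 98 nucleolus genes had a median of -0.39, with 48 at an unadjusted p under 0.05 and lower. Terms were tested with all 6 libraries only, so their dependence on single libraries was not tested. Without the library labelled empty vector RNAi 2, the mean of the fixed peroxisomal list was 0.06 in place of 0.36. That of the ribosomal protein list was -0.12 in place of -0.29.

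With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 0 genes and the highest other split 1, and since any split gives at least 0, that count tells nothing. At an unadjusted p under 0.05 the real split had 1444 genes and the highest other 1037, so 1 of 10 splits, the real one, gave as many. By camera the real split called 20 lists and the highest other 25, and 4 of 10 splits gave at least as many, the real one included.

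The stage of the worms deserves a second look, since the labels say adulthood. Yolk genes were low in all 6 libraries (vit-2 0.16 to 2.49 FPKM, vit-6 0.80 to 21.1 FPKM), as was the adult collagen gene col-19 (0.56 to 3.48 FPKM), while the moulting gene mlt-10 had 39.7 to 314 FPKM. The collagen gene bli-1, in both the adult cuticle and the moulting lists, had 25.6 to 496 FPKM. The adult cuticle list had median FPKM of 605 after hda-5 RNAi and 229 with the empty vector, so col-19 does not stand for that list and the markers disagree. Reads lost to near-identical copies are argued against by vit-6, whose sequence is distinct from the other yolk genes, and by col-19, with at most 21.1 FPKM in any library. Collection before egg production may account for part of it, since the median over 29 early embryonic genes was at most 0.135 FPKM in any library. In each library 10 of the 29 reached 1 FPKM, and the 10 with a mean of at least 1 FPKM had library medians of 10.4 to 13.9 FPKM. Those 10 were picked by their level, and whether they are also expressed outside embryos was not tested. They therefore neither show nor exclude embryos. The stage stays open, and no biological explanation by group was tested.

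Empty vector RNAi 1 lay nearer to the hda-5 RNAi libraries than to the other controls, with root mean square log2 differences of 0.297, 0.418 and 0.600 from hda-5 RNAi 1, 2 and 3, against 0.669 and 0.665 from the libraries labelled empty vector RNAi 2 and 3, which differed from each other by 0.786. That empty vector RNAi 1 is a mislabelled hda-5 RNAi library is argued against by its hda-5 level, 9.78 SD of the hda-5 RNAi group above that group's highest library. For the library labelled empty vector RNAi 2 the same measure was -0.11 SD, within the range of that group, but its distances of 0.676, 0.759 and 0.704 from hda-5 RNAi 1, 2 and 3 exceed the 0.404 to 0.552 among them, so a wrong label and a control that stands apart cannot be told apart. The edgeR columns of the authors' deposited table argue against the libraries labelled empty vector RNAi 2 and 3 being H5-2 and H5-5. In those columns the median absolute log2 difference, with a constant offset taken out, was 0.197 for H5-2 and 0.178 for H5-5, where matched libraries gave 0.001. Control cultures of different age may contribute, since the moulting list of empty vector RNAi 3 deviated by -1.02 from the mean of all libraries, below all 10000 matched random lists, and a batch shared with libraries not analysed here stays open and untested.

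The higher acs-2 and fat-6 values after hda-5 RNAi are a hypothesis to follow up, since neither passed over all genes. For acs-2 the log2 difference was 1.52 against empty vector RNAi 1 alone, so it did not rest on the controls that stand apart. That outcome was close to fixed in advance, since a small limma p favours genes whose controls lie near each other. It is no independent support for an effect of the RNAi. In the scaling alternative farthest from the main 1.39 the log2 difference was 1.46. The scalings left the median of all genes between -0.02 and 0.08, so they could not have removed such a difference and were no test of it. Whether an age difference accounts for the acs-2 values cannot be told from the controls. Over the 3 controls acs-2 spanned 0.24 on the log2 scale while bli-1 spanned 3.79. However, acs-2 was picked by its limma p, which favours genes with a small spread among the controls. The wide span of bli-1 came from empty vector RNAi 3 (25.6 FPKM). In hda-5 RNAi 3, acs-2 (111 FPKM), bli-1 (496 FPKM) and mlt-10 (314 FPKM) were each highest, and an age difference between the groups was not tested. For fat-6 the same single control gave 0.80, below the 1.32 with all controls by more than its SE but above a 50% loss, so the standing apart of the controls cannot be told apart from the RNAi. For H5-2, which matches no library analysed here, the authors' deposited table gives -1.89 for hda-5 but only 0.28 for acs-2 by edgeR. The library labelled empty vector RNAi 2 had hda-5 at 3.22 FPKM, within the range of the hda-5 RNAi libraries, yet acs-2 at 28.7 FPKM. Low hda-5 thus did not always go with high acs-2. An effect of hda-5 RNAi on acs-2 is not settled, and unlabelled culture differences between the groups stay open.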
